A study of Homo sapiens with 2 samples.

How the data were processed

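Gene expression was measured in DLD-1 cells, a human colorectal carcinoma line, on 2 Affymetrix oligonucleotide arrays, 1 per condition. The cells carried a stable tet-off construct for wild-type p53, in which tetracycline in the medium keeps the transgene silent. The p53 off array came from cells kept with tetracycline. The p53 on array came from cells that had been without it for 9 h. Total RNA was prepared with Trizol and labelled by the standard Affymetrix procedure, per the labels' protocols.

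The values deposited by the authors are linear signal intensities, 1 per probe set, made with MAS5 per the submitters' processing notes. The software version, detection calls and background settings are not given in the sources used here. Each column held 54675 probe sets, of which 62 were control probe sets. The mean signal after leaving out the lowest and highest 2% of probe sets was 499.9 on both arrays, so each array had been scaled by 1 factor to a common target near 500. No other normalization between the arrays was visible in the values, and none was added for the main comparison. An array has no read depth. Its precision is limited by the number of arrays, here 1 per condition.

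Probe sets were named from GEO's platform annotation, and symbols were updated through Entrez identifiers to RefSeq names of the GRCh38.p14 assembly. Of the 54613 probe sets that were not controls, 41091 had 1 gene symbol, 1801 had several and 11721 were unnamed here. For 41037 of the 41091 the identifier was found in the RefSeq table. Only probe sets with 1 symbol were used, and they covered 19775 genes. No coordinates are printed, because the build behind the probe sets is not given in the sources used here. The gene that encodes p53 itself stood first in the rule for named genes and is not reported here. Its induction was therefore not checked, and p53 on and p53 off are the conditions as labelled.

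Signals under a floor of 112.4, the median (50th percentile) of all signals that were not controls over both arrays, were set to that floor. Where 1 of the 2 signals was under the floor, the fold is a lower bound and is written "at least". Where both were, there was no ratio and the gene was called not measured. Each gene was represented by its probe set with the highest mean signal, which left 13915 measured genes. The log2 ratio is that of the p53 on signal over the p53 off signal. There were no replicates, so no test, p-value or standard error between the conditions was computed, and genes were counted by size alone, at 2-fold for single genes and at 1.5-fold for members of gene lists.

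The 28 gene lists, the floor, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined. Each list's median log2 ratio was placed among 10000 random lists of the same size, drawn from measured genes outside the list and matched on 20 bins of mean log2 signal. That percentile describes these 2 arrays. The 95% interval beside a list's median is the binomial (order-statistic) interval over its members and leaves out any spread between cultures. The named genes were the 12 with the largest and the 12 with the smallest log2 ratio among genes whose measured probe sets all had the same sign, the 4 members of each list with the largest absolute log2 ratio, and the 8 largest over the 6 p53 target lists together. Members outside this rule that are named in the text were chosen after their values were seen.

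The procedure was tested on simulated data made from the p53 off array, with a noise SD of 0.59 on the log2 ratio, taken from the spread between probe sets of 1 gene. Of 200 changed genes in this simulated comparison, the 2-fold threshold recovered 49.0% of those changed 2-fold, 95.0% of those changed 4-fold and 100.0% of those changed 8-fold. The changed genes were drawn only from bright genes, far above the floor, and all probe sets of a gene were changed alike. Recovery among dim genes was therefore not measured. Of the unchanged genes, 8.11%, 8.00% and 8.16% passed the threshold in the 3 runs. The simulated noise leaves out any spread between cultures, and these shares follow largely from its chosen SD. They are therefore not error rates of the real comparison.

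Other settings, chosen before the data were seen, were floors at the 40th and 60th percentile, no floor with a pseudocount of 1, a pseudocount equal to the floor, centring on the median gene, quantile normalization, loess on mean signal (span 0.3), the mean of all measured probe sets of a gene, and leaving out probe sets whose names mark shared sequence (_x_at and _s_at). Ranges across settings in the text cover these and the processing described above. Scaling to the hybridization spike-ins was added after the data were seen and is given apart. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.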

Results

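The transcriptome of DLD-1 cells with the p53 transgene off was compared with that of the same cells 9 h after tetracycline withdrawal, to show which transcripts differ when wild-type p53 is switched on. DLD-1 is a colorectal carcinoma line whose own p53 is mutated. Each condition was measured on 1 array, so every ratio below describes these 2 arrays and has no replicate check. The median signal was 103.0 on the p53 off array and 121.8 on the p53 on array, and 47.8% and 52.2% of probe sets lay at or above the floor of 112.4. Across all probe sets the log2 signals of the 2 arrays correlated with r = 0.83. Probe sets are not independent replicates.

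With p53 on, 2126 of 13915 measured genes (15.3%) were at least 2-fold higher and 1880 (13.5%) at least 2-fold lower. The large differences were mostly increases, with 184 genes at least 8-fold higher against 19 at least 8-fold lower. For 548 of the higher and 210 of the lower genes the dimmer signal was under the floor, so the ratio is a bound. The median log2 ratio of all measured genes was 0.0035, with an SD over genes of 1.06.

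Among genes whose measured probe sets all had the same sign, the 12 with the largest ratios were ITGB8, EPPK1, REEP1, PMEPA1, NDRG1, ARG2, RNF144B, PRR9, MARCHF3, OSBPL6, IFIT3 and HOXD10. ITGB8, an integrin subunit, had signals of 89.3 with p53 off and 11745 with p53 on and was at least 104.5-fold higher. EPPK1, which encodes epiplakin, a cytolinker of epithelial cells, was 63.2-fold higher, at 398.1 and 25145. NDRG1, a gene induced by p53, hypoxia and differentiation, was 46.2-fold higher at 660.7 and 30535. ARG2, the mitochondrial arginase, was 45.2-fold higher, and RNF144B, a ubiquitin ligase known as a p53 target, 44.8-fold. PMEPA1, an inhibitor of TGF-beta signalling, was at least 50-fold higher and IFIT3, an interferon-induced gene, at least 41.2-fold. The shared sign was a condition of this ranking, so it is no separate support for these genes. NDRG1 and PRR9 had only 1 measured probe set each. The folds of the other genes are those of the brightest probe set, and further measured probe sets gave smaller ratios. Their lowest log2 ratios were 1.07 for ITGB8, 0.38 for EPPK1, 2.99 for PMEPA1, 3.43 for ARG2, 2.18 for RNF144B and 3.34 for IFIT3. For MARCHF3 it was 0.015.

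Under the same condition, the 12 genes with the smallest ratios were PLK1, SERPINH1, KIF23, RNF26, FARSA, ASF1B, PSRC1, UBE2T, UBE2C, UBE2S, HJURP and MYADM. PLK1, a mitotic kinase, was 17.8-fold lower with p53 on, at 5062 and 284.2. KIF23, a kinesin of cytokinesis, was 15.3-fold lower on its brightest probe set, and its other probe set, with a p53 on signal under the floor, was also lower. UBE2C and UBE2S, the ubiquitin-conjugating enzymes of the anaphase-promoting complex, were 10.2-fold lower each. HJURP, the chaperone of the centromeric histone, was 9.74-fold lower, and ASF1B, a histone chaperone of dividing cells, 11.5-fold lower. SERPINH1, a collagen chaperone, was at least 16.1-fold lower. PLK1, SERPINH1, ASF1B, PSRC1, UBE2T, UBE2C, UBE2S and HJURP had only 1 measured probe set each. For these genes the condition of a shared sign was met without any comparison.

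The only repeat measurement was that of several probe sets for 1 gene. A gene's other measured probe sets differed from its brightest one by a median of 0.56 on the log2 scale, with signals under the floor set to it, equal to an SD of 0.84. Among 2207 genes past 2-fold with more than 1 measured probe set, all probe sets had the same sign in 76.2% (exact 95% binomial interval 74.4 to 78.0%). Among all 6676 genes with more than 1 measured probe set, which include those past 2-fold, it was 58.6% (57.4 to 59.8%). Part of this gap follows from selection, because the genes past 2-fold were picked by the ratio of 1 of the compared probe sets. On every one of at least 2 measured probe sets, 359 genes were at least 2-fold higher and 264 at least 2-fold lower.

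The arrays also differed in their control probe sets. The beta-actin 3' signal was 1.37 times the 5' signal on the p53 off array and 7.29 times on the p53 on array, and for GAPDH the ratio was 0.97 and 1.77. The 18 probe sets for hybridization spike-ins were a median of 1.89 times brighter on the p53 on array, with a range from 1.47 to 2.59. If the arrays were scaled to these spike-ins, the median of all measured genes would be -0.80 instead of 0.0035, with 830 genes at least 2-fold higher and 5868 at least 2-fold lower. All directions given here are therefore relative to the median gene.

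**Figure D1:**
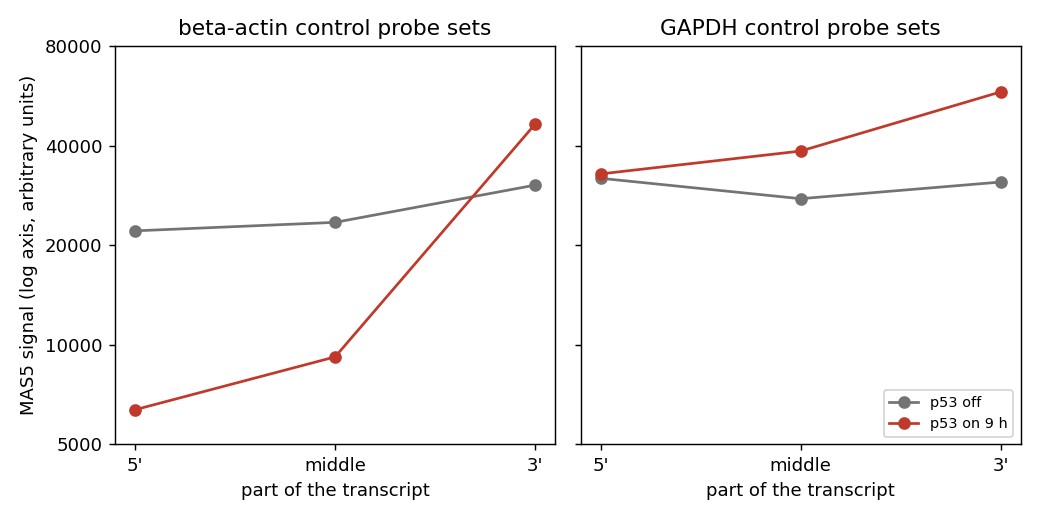
Signal of the 5', middle and 3' control probe sets of beta-actin (left) and GAPDH (right) on the p53 off array (grey) and the p53 on array (red), on a log axis in MAS5 units, 1 point per array. On the p53 on array the beta-actin signal is 46373 at the 3' probe set and 6360 at the 5' one, while on the p53 off array it stays between 22084 and 30357.

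Known p53 target genes were higher as a group. Over the 6 target lists together, 119 members were measured, of which 80 were at least 1.5-fold higher, 7 at least 1.5-fold lower and 32 between. Their median log2 ratio was 0.97 (95% interval over members 0.78 to 1.12), above all 10000 random lists, of whose medians the central 95% lay between -0.28 and 0.12. With the arrays scaled to the spike-ins it was 0.042. It stayed above all random lists, but this rank was nearly fixed in advance. A single factor shifts every gene alike except at the floor. Among all measured genes 25.9% were at least 1.5-fold higher, and 25.9% at least 1.5-fold lower. The 8 members with the largest ratios were HES2, DDIT4, DRAM1, ACER2, KRT15, SERPINB5, VDR and APAF1. DDIT4, an inhibitor of mTORC1, was 16-fold higher, at 440.8 and 7064, DRAM1, a lysosomal protein of autophagy, 13.5-fold, and SERPINB5, the gene of maspin, 11.9-fold.

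In the cell cycle arrest list, 9 of 14 measured genes were at least 1.5-fold higher and 1 was lower. CDKN1A, the gene of the p21 inhibitor of cyclin-dependent kinases, was 8.58-fold higher on its single probe set, at 2723 and 23349. SFN, which encodes 14-3-3 sigma, was 3.59-fold higher at 20267 and 72704, and GADD45A 2.75-fold higher. GDF15, a secreted cytokine of the TGF-beta family, was the member that was lower, 5.79-fold on its brightest probe set (13288 and 2295). Its other measured probe sets were dim and went the other way, by 1.22 and 0.23 on the log2 scale. The list median was 0.92, at the 99.9th percentile of random lists.

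In the apoptosis list, 13 of 22 measured genes were at least 1.5-fold higher and 3 lower, with a median of 0.80 at the 99.8th percentile. APAF1, the scaffold of the apoptosome, was 10.7-fold higher, TP53I3 5.52-fold, and the death receptor genes FAS and TNFRSF10B 5.49-fold and 4.19-fold. BAX, a mitochondrial pore former, did not follow them, with log2 ratios of -0.34 and -0.091 on its probe sets. The 3 lower members were TNFSF9, a cytokine gene, at a log2 ratio of -1.92, SIAH1 at -0.65 and TP53AIP1 at -0.64. Among regulators of p53, 9 of 12 were at least 1.5-fold higher and 2 lower, the ubiquitin ligase genes RCHY1 (-0.96) and SIAH1. MDM2, the ubiquitin ligase that degrades p53, was 5.76-fold higher on its brightest probe set, and all 10 of its measured probe sets were higher. The median of this list was 0.98, at the 99.7th percentile.

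Of the metabolism, redox and autophagy targets, 15 of 18 were at least 1.5-fold higher and none was lower by that size, with a median of 1.01 at percentile 99.97. SESN1, of the sestrin family, was 6.72-fold higher, and ACER2, a ceramidase, 12.4-fold. ULK1, a kinase that starts autophagy, was at least 7.78-fold higher. The list of other often reported targets held 37 of 47 higher genes and none lower, with a median of 1.30. The DNA repair and nucleotide list did not stand apart, with a median of 0.36 (0.33 to 0.55 across settings) at percentile 94.1. There, POLH, a translesion polymerase, was 5.85-fold higher while POLK, another one, was 4.30-fold lower and FANCC, of the Fanconi anaemia pathway, 2.54-fold lower.

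**Figure D2:**
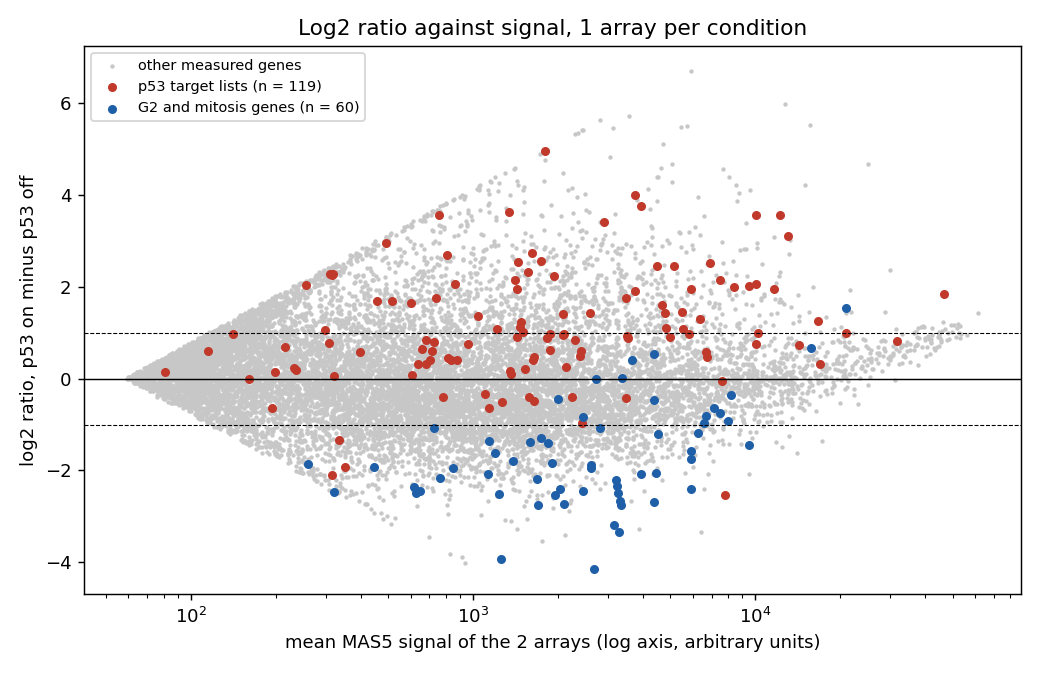
Log2 ratio (p53 on minus p53 off) of each measured gene against its mean MAS5 signal over the 2 arrays (log axis), 1 point per gene, with dashed lines at 2-fold and, at low signal, sloping edges that come from the floor. The 119 measured p53 targets (red) lie mostly above 0 and the 60 measured G2 and mitosis genes (blue) mostly below.

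Genes of cell division were lower as a group. Of 60 measured G2 and mitosis genes, 51 were at least 1.5-fold lower and 2 at least 1.5-fold higher, and 45 were at least 2-fold lower. Their median log2 ratio was -1.87 (95% interval over members -2.19 to -1.39), below all 10000 random lists. Besides PLK1, KIF23 and UBE2C, AURKA, a kinase of the spindle poles, was 9.08-fold lower on its brightest probe set. CCNB1, the cyclin B1 gene, had a log2 ratio of -2.41, and MKI67, a proliferation marker, of -1.94. The exceptions past 1.5-fold were BUB3, a checkpoint protein gene, at 1.55 and PTTG1, the securin gene, at 0.66.

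G1/S and replication genes were also lower, to a smaller extent. Of 60 measured members, 44 were at least 1.5-fold lower and 2 at least 1.5-fold higher, with a median of -1.12 (-1.57 to -0.79), below all random lists. MCM10 and MCM3, of the replication machinery, were 8.30-fold and 7.36-fold lower. ATAD2, a chromatin ATPase, was 6.34-fold lower with all 4 of its probe sets lower, and UHRF1, which maintains DNA methylation, 5.81-fold. RRM1, the large subunit of ribonucleotide reductase, had a log2 ratio of 0.81, and E2F1, a regulator of S phase entry, of 0.91 on its brightest probe set but -1.47 on another.

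Ribosome biogenesis genes were lower, 22 of 40 by at least 1.5-fold and 3 higher, with a median of -0.70 (-1.10 to -0.28), below all random lists. The 3 higher genes were UBTF, POLR1A and NPM1, at log2 ratios of 1.21, 1.06 and 0.93 on their brightest probe sets. BYSL and NOB1, which act in small subunit maturation, were 4.37-fold and 4.11-fold lower. Mitochondrial ribosomal proteins were lower in 28 of 52 cases and higher in 2 (MRPL33 and MRPL18), with a median of -0.71, below all random lists. Their median was -0.33, at the 6.69th percentile, without probe sets marked for shared sequence. MRPL44 was 5.80-fold and MRPS12 4.87-fold lower. Cytosolic ribosomal proteins had a median of 0.79, with 26 of 34 at least 1.5-fold higher and none lower, but their median was -0.023 after quantile normalization and 0.43, at percentile 93.0, without probe sets marked for shared sequence. RPS27 was 2.12-fold higher at 30020 and 63682. Respiratory chain subunits had a median of 0.0076 (-0.028 after quantile normalization and -0.016 without probe sets marked for shared sequence), with 4 of 48 higher (NDUFB2, NDUFB6, NDUFB8 and COX4I1) and 7 lower, led by NDUFS3 at 2.44-fold lower.

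Immediate early genes were mixed, with 18 of 33 at least 1.5-fold higher and 7 lower. Their median was 0.76 (interval over members 0.070 to 1.55, and 0.50 to 0.94 across settings), above all random lists. HBEGF, a ligand of the EGF receptor, was 8.28-fold higher, JUNB 6.89-fold and EGR1 6.62-fold, while MYC had a log2 ratio of -1.71. Of 21 measured interferon response genes, 10 were at least 1.5-fold higher and 3 lower. Their median was 0.54 (interval over members -0.22 to 2.16) at percentile 99.2, or percentile 97.2 after loess. Across settings the median ran from 0.44 to 1.02, but the interval over members held both signs. The lower ones were HERC5, IFI6 and IRF9, at log2 ratios of -0.98, -0.90 and -0.67. After IFIT3, ISG20, an exonuclease, was at least 9.96-fold higher and IFIH1, a sensor of viral RNA, 9.15-fold. Hypoxia and glycolysis genes had a median of 0.43 at percentile 97.2, with an interval over members of -0.17 to 0.998 that also held both signs. Across settings the median was 0.17 to 0.48, at percentiles 88.1 to 98.2. Of 30 genes, 14 were higher and 5 lower, of which PFKP, a phosphofructokinase gene, had the smallest log2 ratio at -1.47. The other lower ones were HK2, PFKL, P4HA1 and PKM. NDRG1, ADM, a vasodilator peptide gene (16.4-fold), ANGPTL4 (7.41-fold) and PFKFB3 (7.38-fold) were the largest in that list.

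Most markers of other cell types were dim on both arrays. Of 11 measured leukocyte markers, 6 were at least 1.5-fold higher and none lower by that size. Their median was 0.61 (interval over members -0.21 to 0.92) at percentile 97.3, but 0.19 at percentile 67.5 with the floor at the 60th percentile. The largest ratio was that of LAPTM5, with signals of 62.7 and 247.9. Fibroblast markers had a median of 0.38 over 8 genes and endothelial markers of 0.34 over 7, at percentiles 86.1 and 83.2. Across settings these medians ran from 0.27 to 0.87 and from 0.083 to 0.54, at percentiles 79.1 to 98.5 and 36.0 to 89.7. The list of 26 reference genes had a median of 0.036, but -0.33 at percentile 1.03 after quantile normalization and -0.13 after loess, with TUBB 2.55-fold lower and GAPDH 2.15-fold higher. The GAPDH difference depended on the part of the transcript. Its 3' control probe set read 31016 with p53 off and 58079 with p53 on, and its 5' one 31837 and 32829.

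**Figure D3:**
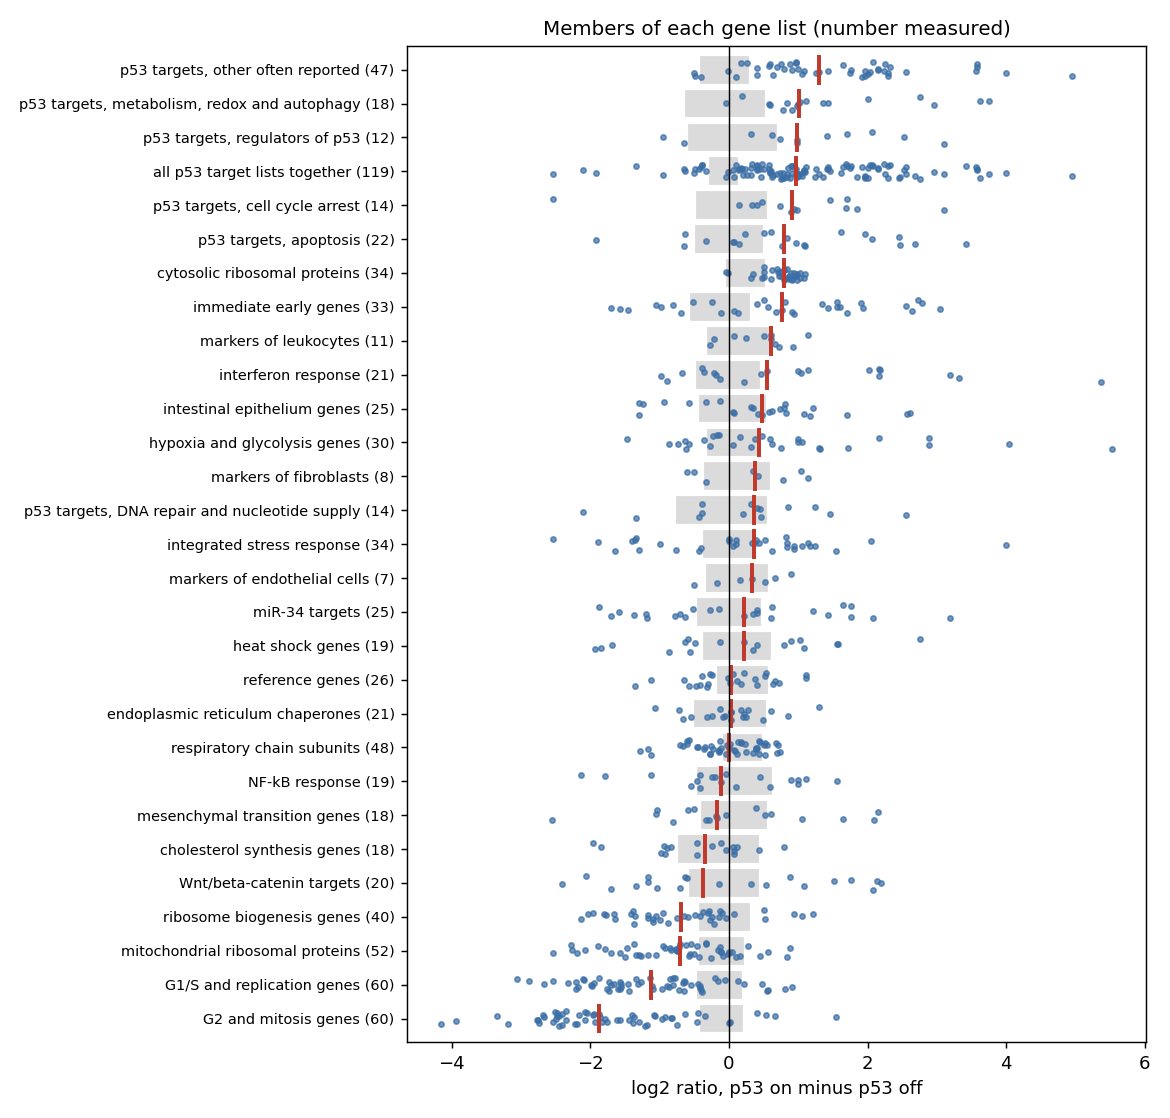
Log2 ratio (p53 on minus p53 off) of the measured members of each gene list, 1 blue point per gene, with the list's median as a red line and the central 95% of the medians of 10000 signal-matched random lists as a grey box, and the number of measured members in parentheses. Medians run from -1.87 for G2 and mitosis genes to 1.30 for the p53 targets in the list of others often reported.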

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

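The tests in this part were set after the ratios were known but before their own outcomes were seen. The stricter reading that leaves loss of signal away from the 3' end open for all 3 patterns, and scaling for the third, was chosen after the outcomes were seen.

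Control probe sets, which enter no gene comparison, differed between the arrays. On the p53 on array the 3' signal of beta-actin was 7.29 times its 5' signal, against 1.37 on the p53 off array, and that of GAPDH 1.77 times, against 0.97. Hybridization spike-ins were 1.89 times brighter on the p53 on array. The probe set for Alu repeats was 2.68 times brighter, at 33465 and 89749.

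The first pattern is the lower signal of G2 and mitosis genes. Over the 31 members with more than 1 measured probe set, the highest ratio per gene had a median of -0.64 (95% interval -1.62 to -0.33), against -0.010 to 0.74 in matched random genes. This bound, set in advance, does not exclude loss of signal away from the 3' end, because transcripts that lost more signal in all their probe sets would give the same. Cross-hybridizing probe sets are argued against, since the median was -1.68 without those marked for shared sequence, below all random lists. The loss cannot be told apart from p53 itself or any other difference between the 2 cultures, because each condition has 1 array.

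The second pattern is the higher signal of p53 targets. Over the 71 members with more than 1 measured probe set, the lowest ratio per gene had a median of 0.18 (-0.092 to 0.49), above the -0.75 to -0.27 of matched random genes. Transcripts that kept more of their signal than others in all their probe sets would give the same, so escape from the 3' bias stays open. Cross-hybridizing probe sets are argued against, since without those marked for shared sequence the list median was 0.98, above all random lists. Escape from the bias, the expression of p53 and other differences between the cultures cannot be told apart with 1 array per condition.

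The third pattern is the higher signal of cytosolic ribosomal proteins, which are among the brightest probe sets. A scaling that differs for bright probe sets cannot be told apart from a change in these genes, because the methods disagree. After loess the median was 0.29 (0.16 to 0.35) instead of 0.79, which alone would count against scaling as the whole cause, but quantile normalization, another correction of the same trend, left -0.023. Loss of signal away from the 3' end also stays open. The lowest ratio per gene over 20 members had a median of -0.012 (-0.40 to 0.28), at percentile 98.1 of matched genes, and is read in the same way.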

How the results depend on the processing

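Spike-in scaling was added after the data were seen, and all other alternatives were chosen before. The counts of genes at least 2-fold higher and lower stayed within 1.5 times under the planned settings except without a floor, where 4741 were higher and 3666 lower among 19775 genes. Under spike-in scaling they were 830 and 5868. The median of all genes was 0.024 and -0.033 with floors at the 40th and 60th percentile, 0.042 without a floor, -0.072 after quantile normalization, 0.051 after loess, -0.017 with the mean of all probe sets, 0.038 without probe sets of shared sequence and -0.80 with spike-ins. The share of 2-fold genes whose probe sets had the same sign was 67.8% and 83.4% with the lower and higher floor, 53.1% without a floor, 78.3% with the pseudocount, 78.1% after loess, 95.9% with the mean of all probe sets and 87.3% with spike-ins. The mean is made from the same probe sets that are compared with it, which raises its share. Spike-in scaling moves all ratios down together, which can also raise the share. The median of the p53 targets lay between 0.90 and 1.07, that of G2 and mitosis genes between -1.87 and -1.68 and that of G1/S genes between -1.16 and -0.98 under all planned settings. With spike-ins these medians were 0.042, -2.78 and -2.11. Each stayed on the same side of all random lists, which a single factor could hardly change. Of the 14 list medians outside the central 95% of random lists, spike-in scaling turned those of apoptosis targets (-0.24), immediate early genes (-0.16), the integrated stress response (-0.56) and cytosolic ribosomal proteins (-0.13), by the construction of a single factor. Quantile normalization turned the last (-0.023). Counting also the lists inside that range, 15 of 29 medians changed sign with spike-ins, 6 after quantile normalization, 2 after loess, 1 with the mean of all probe sets and 2 without probe sets of shared sequence. Without probe sets of shared sequence, GDF15 (1.22), PDIA4 (1.03) and TSR1 (0.20) changed sign because another probe set stood for the gene. No paired analysis was possible because each condition has 1 array. The signal over background limits the ratios of dim genes, for which the 112.4 floor gives bounds only.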

Other observations

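The test on the integrated stress response in this part was chosen only after the result was seen.

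Genes of Wnt/beta-catenin signalling, which is active in this line, went both ways. Of 20 measured targets, 10 were at least 1.5-fold lower and 7 at least 1.5-fold higher, with a median of -0.37 at percentile 12.7 of random lists. Across settings that percentile ran from 1.41 to 89.9, and without probe sets marked for shared sequence the median was 0.32. BMP4 was 5.29-fold lower, and the intestinal stem cell gene LGR5 had a log2 ratio of -2.06. APCDD1 was at least 4.57-fold higher, SP5 4.40-fold and CD44 4.21-fold, with all 10 measured probe sets of CD44 higher. Intestinal epithelium genes had a median of 0.48 at percentile 95.9 (0.18 to 0.53 across settings, at percentiles 88.9 to 98.8), with 11 of 25 higher and 4 lower, led by LGALS4, the galectin-4 gene, at 6.09-fold higher. Among mesenchymal transition genes 5 of 18 were higher and 5 lower, with TCF4 5.86-fold lower and SNAI2 4.43-fold higher. Reported targets of miR-34, a microRNA family induced by p53, had a median of 0.22 at percentile 85.3, with 9 of 25 higher and 9 lower, but -0.11 after quantile normalization and -0.27 with the mean of all probe sets. ULBP2, a ligand of a natural killer cell receptor, was 9.07-fold higher there, and CCNE2 3.67-fold lower.

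NF-kB response genes had a median of -0.11 (-0.24 to -0.059 across settings) at percentile 24.2, with 6 of 19 at least 1.5-fold higher and 3 lower. TNFAIP2 was 2.93-fold higher. ICAM1 was at least 4.37-fold lower, NFKBIA 3.45-fold lower and CXCL3 at least 2.18-fold lower. Cholesterol synthesis genes had a median of -0.35 (-0.50 to -0.16 across settings) at percentile 30.9, with 1 of 18 higher (TM7SF2) and 7 lower, led by SQLE at 3.89-fold lower. Heat shock genes had a median of 0.22 at percentile 74.9, but -0.17 after quantile normalization and -0.028 after loess, with 7 of 19 higher and 6 lower. There the chaperone genes STIP1, FKBP4 and DNAJB1 were 3.83-fold, 3.60-fold and 3.22-fold lower, and HSPA6 6.72-fold higher. Endoplasmic reticulum chaperones had a median of 0.029 at percentile 58.0 (-0.024 to 0.14 across settings), with 3 of 21 higher and 3 lower.

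Tetracyclines act on mitochondrial translation, so withdrawal of the drug could by itself relieve an integrated stress response in these cells. The lower signals of GDF15 (5.79-fold on its brightest probe set) and PPP1R15A (3.69-fold) raised this hypothesis. It predicts that the other genes of that response are lower too. The whole list had a median of 0.36 at percentile 97.7, but 0.095 at percentile 69.2 without probe sets marked for shared sequence. Without members of the p53 target lists, the 31 measured genes had a median of 0.34, at percentile 95.8 of random lists. Under the rule written for this test, a median above the middle of the random lists counted against the hypothesis. That rule is not followed here, because members went both ways. The 95% interval of their median (-0.41 to 0.83) reached below the random range (-0.37 to 0.40), so the hypothesis stays open. CHAC1 was 4.14-fold higher. Mitochondrial ribosomal proteins, with a median of -0.71, were not part of this test, and no array of cells without the transgene was analysed here.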
